A study of Homo sapiens with 10 samples.

How the data were processed

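RNA from HEK293T cells was sequenced after 24 h of BRSK1, BRSK2 or hcRED overexpression and from mock samples, with 3 µg of RNA per sample sent for sequencing, per the labels. Samples were grouped by the genotype given in the labels, and replicate numbers were taken from the sample titles. The labels give hcRED as replicates 1 and 3 and Mock as replicates 2 and 3. The submitters' processing notes name STAR, edgeR and limma and the build hg38, without versions or the order of steps, and the read counter, its strand setting and the annotation release are not given in the sources used here.

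The authors deposited a table of raw read counts per gene for each kinase, with its 3 libraries and the 4 control libraries. The control columns held the same counts in both tables (0 genes differed), so the tables were joined on the gene ID into 10 libraries of 58676 genes, with no blank or total lines (0) and no unused count column (0). The authors also deposited log2 CPM values of the genes in their result tables, which served only as a check, library by library, against log2 CPM computed from the counts. The authors' deposited table of differential expression for each kinase gives a log2 fold change, a p-value, an adjusted p-value and limma's scores (the moderated statistic and log odds), named so per the file headers, and lists only genes with an adjusted p under 0.05. The scores were not used. Gene symbols are those of the deposited tables, with older symbols matched through a table of gene names (58207 IDs had a current symbol), and gene positions are those in the deposited tables on hg38.

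Each comparison was tested with edgeR's quasi-likelihood F test on the counts as deposited (edgeR 4.0.16, R 4.3.3): TMM factors, filterByExpr with a minimum count of 10 and a minimum total of 15, estimateDisp, and glmQLFit and glmQLFTest with robust estimation. One fit with 4 group means held all 10 libraries, so that groups of 2 and 3 share one estimate of spread (biological coefficient of variation 8.1%). The kinases were each compared with the mean of the hcRED and Mock groups, then with each other, and hcRED with Mock. Benjamini-Hochberg adjustment ran over the 16936 tested genes, with a threshold of 0.05 and no fold threshold. Log2 fold changes are those of glmQLFTest with its prior count left at the default, and the standard error is the absolute log2 fold change divided by the square root of F. A prior count of 2 was used only for log2 CPM, in the principal components, the correlations between libraries and the GC trends. Group levels are means ± SD in CPM, of total counts for BRSK1 and BRSK2 in the account of the overexpressed genes and TMM-scaled otherwise.

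In all, 42 gene lists of 1148 symbols (0 unmatched) covered stress responses, signalling targets, metabolism, organelles, the cell cycle and markers of other cell types. Each list had at least 5 tested members and was tested with camera (limma 3.58.1, preset correlation 0.01), with camera and an estimated correlation, and with fry, adjusted over the lists. The lists, the tests, the design, the alternatives, except those named below as added, and the rule for named genes were set before the data were examined. The rule names BRSK1 and BRSK2, the 8 highest and 8 lowest genes called with a mean of at least 5 CPM and with the libraries of both sides fully apart, any NRF2 target, up to 4 members of each other list with the smallest p, and for hcRED against Mock the 5 genes with the smallest p. Genes linked to sex, here XIST, TSIX and genes on the Y chromosome, are never named. The text names a selection of these, and KRT6A, DSC3, TUBB3, TUBA8 and TUBB2B outside the rule, which were chosen after their values were seen.

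The alternatives were RLE and upper quartile factors, library totals alone, BRSK1 and BRSK2 left out of the scaling, no filter or one of 1 CPM in at least 3 libraries, DESeq2 1.42.0, limma-voom, no robust estimation, the replicate number as a block, each library left out, an adjusted p under 0.01, a fit of only the groups compared, and hcRED alone, Mock alone or all 4 controls as 1 group. Removal of each library's trend with GC content, or with GC content and gene length (lowess, span 0.3), was added after the data were seen, with both taken from the longest GENCODE 29 transcript of each gene (protein-coding transcripts first; all tested genes had a value), as were list tests without single libraries or against a single control. Where leaving out a library left a group with 1 sample, that sample was assumed to vary like the other groups. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

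The steps were tested on simulated data drawn from the real means and library sizes, over 16452 genes. Changes were placed only in genes with a control mean over 5 CPM, so recovery of genes at lower levels was not tested. For BRSK2 against the controls the test recovered 94% of the genes changed by 0.5 on the log2 scale and 100% of those changed by 1 or 2, with 8 false calls. For BRSK1 it recovered 91% at 0.5 and 100% at 1 and 2, with 7 false calls. For BRSK2 against BRSK1 it recovered 90.1% at 0.5 and 100% at 1, with 21 false calls, and for hcRED against Mock, with no change simulated, it made 0 calls, as did limma-voom (0), while DESeq2 made 1. A list of proteasome subunits shifted by -0.2 was found by camera (adjusted p = 1.88e-10, with 1 other list called), with an estimated correlation (adjusted p = 0.00845, with 0 other lists called) and by fry (adjusted p = 2e-05, with 3 other lists called). Each gene was drawn independently, so this does not show how the list tests behave where the genes of a list vary together. Depth was 16516116 to 24304302 counts per library, and log2 expression correlated at 0.9857 or more within groups. Within each group every pair of libraries differed by more than sampling noise (chi-square per degree of freedom 3.93 to 16.57), so no pair was taken for 1 library deposited more than once. This does not show that the libraries came from separate cultures. Counts per gene cannot separate near-identical paralogs, pseudogenes or overlapping genes, and without a stated strand setting antisense pairs are uncertain too.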

Results

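RNA was sequenced from 10 libraries of HEK293T, a transformed human embryonic kidney cell line. Per the labels, 3 samples overexpressed BRSK2 and 3 overexpressed BRSK1, both AMPK-related serine/threonine kinases, for 24 h. The control groups were 2 samples with hcRED, a red fluorescent protein, also for 24 h, and 2 mock samples (Mock). The total counts per library were 18995616, 21228385 and 16516116 for BRSK2 replicates 1, 2 and 3, and 20685724, 22691687 and 24304302 for BRSK1 replicates 1, 2 and 3. The hcRED libraries held 20365834 (replicate 1) and 19410607 (replicate 3) counts, and the Mock libraries 19536244 (replicate 2) and 20029269 (replicate 3). A gene was tested if it passed a filter on low counts, which left 16936 of the 58676 genes in the tables. The labels do not state that the samples came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. The series title names both kinases as negative regulators of NRF2, the transcription factor of the antioxidant response, and the comparisons ask what each kinase changed against the controls and where the kinases differed.

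The overexpressed genes were looked at first. BRSK2 (ENSG00000174672; hg38 chromosome 11, plus strand, 1389899 to 1462689; protein coding) stood at 88120 ± 17015 CPM (of total counts) in the BRSK2 libraries (SD, n = 3), which was 8.81% ± 1.70 of all counts. Elsewhere it stood at 79.8 ± 6.01 in BRSK1 (n = 3), 77.1 ± 5.09 in hcRED (n = 2) and 97.1 ± 2.75 in Mock (n = 2). BRSK1 (ENSG00000160469; hg38 chromosome 19, plus strand, 55282072 to 55312533; protein coding) stood at 60660 ± 11903 CPM in the BRSK1 libraries, or 6.07% ± 1.19 of all counts. Its level was 19.9, 28.2 and 27.0 CPM in the BRSK2 libraries, 23.6 ± 7.24 in hcRED and 12.3 ± 2.79 in Mock. Against the controls the log2 fold change was 10.10 ± 0.14 (SE) for BRSK2 (adjusted p = 7.83e-23) and 11.84 ± 0.30 for BRSK1 (adjusted p = 2.43e-06). BRSK1 was at 0.66 ± 0.24 in BRSK2 cells (adjusted p = 0.157), which did not pass here but passed without robust estimation (adjusted p = 0.0226) and without BRSK1 replicate 1 (0.0439), and lay between 5.16e-06 and 0.761 over all alternatives run. BRSK2 was at -0.08 ± 0.11 in BRSK1 cells (adjusted p = 0.734), and passed in none of the alternatives run (adjusted p from 0.23). The counts per gene do not separate introduced from endogenous transcript.

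**Figure D1:**
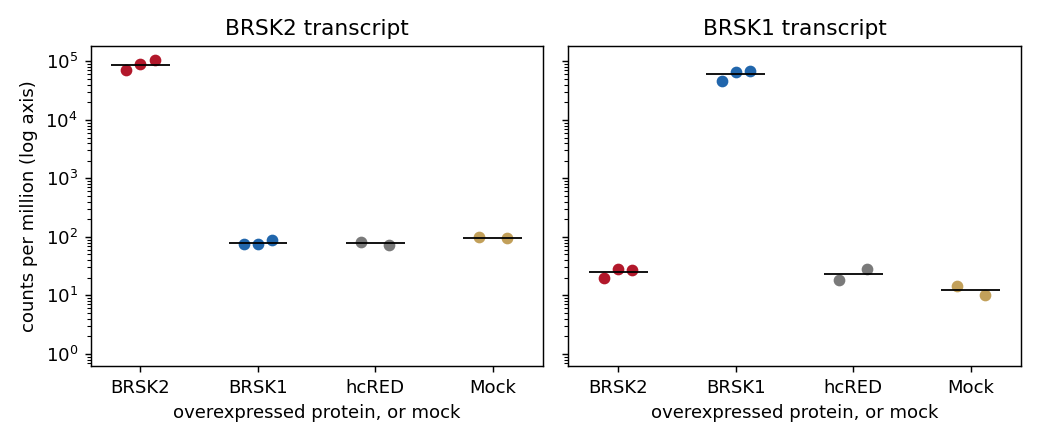
CPM of total counts (log axis) of BRSK2 (left) and BRSK1 (right) in each library, grouped by what was overexpressed; points are libraries and bars group means (n = 3, 3, 2 and 2). The BRSK2 libraries lie between 69928 and 103644 for BRSK2 and the BRSK1 libraries between 47151 and 69608 for BRSK1, with the other libraries below 100.

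To find what BRSK2 changed, its 3 libraries were compared with the mean of the hcRED and Mock groups (2 libraries each). WNT9A, a secreted Wnt ligand, rose 3.19-fold (log2 fold change 1.67 ± 0.13 SE, adjusted p = 2.5e-08). ZC3H12A, an endoribonuclease that degrades inflammatory transcripts (1.64 ± 0.17), RELB, an NF-kB subunit (1.53 ± 0.16), and DUSP8, a phosphatase of MAP kinases (1.40 ± 0.16), followed it. AMOTL2, a cell junction protein of the angiomotin family (1.18 ± 0.12), the kinase PIM1 (1.16 ± 0.09), RNF165 (1.14 ± 0.18) and RENBP (1.08 ± 0.15) also rose. The decreases were smaller, with TMEM255A at -0.88 ± 0.14, ZNF587B at -0.75 ± 0.15, FGD6 at -0.71 ± 0.13 and SLITRK3 at -0.66 ± 0.13. In all, 1325 genes passed edgeR's quasi-likelihood test at an adjusted p under 0.05, 808 higher and 517 lower, with a median absolute log2 fold change of 0.34. Of these, 84 were more than 2-fold higher and 7 more than 2-fold lower.

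Targets of several signalling pathways were called higher with BRSK2 by camera, which also called 13 of the 42 lists between hcRED and Mock. Of 27 tested immediate early genes, the first transcripts induced by growth factors and stress, 12 rose and 15 did not pass (17 rose adjusted over the list alone), among them DUSP1 (1.07 ± 0.09), JUNB (0.80 ± 0.11) and NR4A1 (0.61 ± 0.10). The list's median was 0.42 (camera adjusted p = 2.34e-16; adjusted p = 0.105 with an estimated correlation). Of 15 NF-kB targets, 5 rose (7 adjusted over the list alone), including RELB and NFKB2 (0.63 ± 0.10). Of 16 TGF-beta and BMP targets, 6 rose (7 adjusted over the list alone), including SMAD7, an inhibitor of that pathway (0.81 ± 0.08), KLF10 (0.80 ± 0.11) and PMEPA1 (0.52 ± 0.11). The camera adjusted p was 0.000101 for the NF-kB list and 2.26e-05 for the TGF-beta list, and for each the adjusted p = 0.105 with an estimated correlation. Of 19 Notch targets, 5 rose, among them the transcriptional repressor HEY2 (0.62 ± 0.11), while 8 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.000158; adjusted p = 0.105 with an estimated correlation). YAP and TAZ targets had 4 of 19 higher, 6 adjusted over the list alone (camera adjusted p = 0.00404; adjusted p = 0.105 with an estimated correlation), and that call was lost against Mock alone (adjusted p = 0.0726). CREB and CRTC targets had 2 of 17 higher, and 2 adjusted over the list alone (camera adjusted p = 0.0063; adjusted p = 0.19 with an estimated correlation). These lists overlap: the 2 CREB and CRTC calls, DUSP1 and NR4A1, are also in the immediate early list, as is KLF10, so they are not separate evidence for each pathway.

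Stress, cell cycle and apoptosis lists were also called with BRSK2. Of 38 ATF4 and integrated stress response targets, 8 rose and 1 fell (11 and 2 adjusted over the list alone), with CHAC1, a glutathione-degrading enzyme, at 0.95 ± 0.15, SESN2 at 0.64 ± 0.08, and PSAT1, an enzyme of serine synthesis, at -0.30 ± 0.06. Its median of 0.08 (camera adjusted p = 0.00232; adjusted p = 0.187 with an estimated correlation) turned to -0.02 under library totals alone. Of 38 G1 and S phase genes, 7 rose and 2 fell (11 and 2 adjusted over the list alone), with the replication licensing factor CDT1 at 0.85 ± 0.07 and E2F1 at 0.62 ± 0.06. That list's median of 0.08 (camera adjusted p = 0.0067; adjusted p = 0.3 with an estimated correlation) turned to -0.03 under library totals, where the list did not pass (adjusted p = 0.323). Of 36 G2 and M phase genes, 7 fell and 29 did not pass (13 fell adjusted over the list alone), with a median of -0.12 (camera adjusted p = 4.84e-05; adjusted p = 0.105 with an estimated correlation). BBC3, a pro-apoptotic BCL2 family member, rose by 0.92 ± 0.10. Its list of 18 had 4 higher and 1 lower, 5 and 1 adjusted over the list alone (camera adjusted p = 0.0313; adjusted p = 0.19 with an estimated correlation). That call was lost without BRSK2 replicate 2 (adjusted p = 0.0684), BRSK2 replicate 3 (0.0541), hcRED replicate 1 (0.0736) or Mock replicate 3 (0.0554). It was also lost against hcRED alone (0.0746), under library totals (0.072) and with a correction for GC content (0.0945). Of 21 snoRNA host and other NMD-sensitive transcripts 0 passed singly, and 0 adjusted over the list alone, while the list's median was 0.21 (camera adjusted p = 0.000384; adjusted p = 0.524 with an estimated correlation). Without BRSK2 replicate 1, SNHG1 (adjusted p = 0.000588), EPB41L4A-AS1 (0.00062), TAF1D (8.35e-05) and SNHG16 (0.00735) were called higher, and by DESeq2 SNHG1 (0.0434) and EPB41L4A-AS1 (0.0291). Over all alternatives run their adjusted p reached 0.406, 0.31, 0.476 and 0.486.

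Cytoskeletal and protein turnover genes were among those that fell with BRSK2. Of 28 tubulins and microtubule-associated proteins, 7 fell and 1 rose (11 and 2 adjusted over the list alone), with TUBB2A at -0.57 ± 0.08, TUBA1A at -0.56 ± 0.06 and TUBB4B at -0.46 ± 0.08. The camera adjusted p was 3.39e-05, and the adjusted p = 0.19 with an estimated correlation. Tubulin genes are close paralogs, so the split of counts between single members is uncertain. Of 34 proteasome subunits and assembly factors, 7 fell, among them the assembly chaperone POMP (-0.31 ± 0.06), while 9 fell and 1 rose adjusted over the list alone (camera adjusted p = 2.26e-05; adjusted p = 0.19 with an estimated correlation). Of 25 heat shock response genes, 5 fell (7 adjusted over the list alone), including the HSP40 co-chaperone DNAJA1 at -0.38 ± 0.06 (camera adjusted p = 0.0137; adjusted p = 0.201 with an estimated correlation). That call was lost without Mock replicate 2 (adjusted p = 0.0544) and against Mock alone (0.0874). Of 24 glycolysis genes, 5 fell and 1, ENO2 (0.47 ± 0.10), rose, with 8 and 4 adjusted over the list alone. The glycolysis call (camera adjusted p = 0.0365; adjusted p = 0.757 with an estimated correlation) was lost without BRSK2 replicate 3 (adjusted p = 0.309), hcRED replicate 1 (0.327) or Mock replicate 2 (0.125), and against hcRED alone (0.971). Of 72 nuclear-encoded respiratory chain genes, 5 fell, the same number as adjusted over the list alone, with UQCR11 at -0.49 ± 0.10 (camera adjusted p = 0.0108; adjusted p = 0.866 with an estimated correlation). That call was lost without BRSK2 replicate 1 (adjusted p = 0.53), hcRED replicate 1 (0.206) or Mock replicate 2 (0.669).

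Of the 18 lists called with BRSK2, 10 higher and 8 lower, none held with an estimated correlation and 14 also passed fry, in the same direction. Between hcRED and Mock camera called 13 lists, of which 0 held with an estimated correlation and 0 passed fry. The count of genes called depended on single libraries: it was 346 without BRSK2 replicate 3, 641 without BRSK2 replicate 2, 2211 without BRSK2 replicate 1, 647 without hcRED replicate 1, 800 without hcRED replicate 3 and 776 without Mock replicate 3. Against hcRED alone 606 genes passed, and against Mock alone 931. Scaling by library totals alone, in which the BRSK2 transcript takes its share of each total, shifted the median of all genes by -0.102 and called 494 genes higher and 2507 lower. In the authors' deposited table for BRSK2, 723 genes were listed, 520 higher and 203 lower, with adjusted p up to 0.0498. All 723 of the authors' deposited table had the same direction here and 709 were called.

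For the question in the series title, the fixed list of NRF2 targets was tested with each kinase. SLC7A11, the cystine transporter subunit that supplies glutathione synthesis (ENSG00000151012; hg38 chromosome 4, 138164097 to 138242349), fell with both, at -0.55 ± 0.09 with BRSK2 (adjusted p = 0.000679) and -0.57 ± 0.09 with BRSK1 (adjusted p = 0.000798). Its call held under each alternative run, with adjusted p up to 0.0123 and 0.0179. Of the 38 tested targets, 5 fell with BRSK2 and 33 did not pass (2 rose and 6 fell adjusted over the list alone). With BRSK1, 3 fell and 35 did not pass (3 fell adjusted over the list alone). The other calls with BRSK2 were GCLM, the modifier subunit of glutathione synthesis (-0.33 ± 0.07), the ferritin light chain FTL (-0.28 ± 0.06), ME1 (-0.27 ± 0.08) and BLVRB (-0.30 ± 0.09). With BRSK1 they were EPHX1 (-0.29 ± 0.07) and FTL (-0.26 ± 0.06), which has processed pseudogenes and is uncertain to that extent. The targets NQO1 (-0.34 ± 0.16, adjusted p = 0.211), HMOX1 (-0.24 ± 0.09, adjusted p = 0.102) and TXNRD1 (-0.16 ± 0.06, adjusted p = 0.0714) did not pass with BRSK2. Nor did they with BRSK1, at -0.16 ± 0.16, 0.12 ± 0.09 and -0.07 ± 0.05. With BRSK2, HMOX1 passed under library totals alone (adjusted p = 0.00994), with no filter (0.0486), without BRSK2 replicate 2 (0.0468), with the correction for GC content (0.0415) and with that for GC content and length (0.0202). TXNRD1 passed under library totals alone (adjusted p = 0.00397), by DESeq2 (0.0345) and with the correction for GC content and length (0.0385). ABCC2, a transporter, stood at 0.90 ± 0.28 with BRSK2 (adjusted p = 0.0522) and passed with the filter at 1 CPM (0.0491), without hcRED replicate 3 (0.0356) and with the corrections for GC content (0.0485) and for GC content and length (0.0423). The replicate number as a block also called HMOX1 and TXNRD1 lower and ABCC2 higher with BRSK2. In all, 14 of the 33 targets without a call for BRSK2 passed in at least 1 alternative, 3 of them higher and 11 lower, of which 7 passed under library totals alone and in no other. Over all alternatives run the adjusted p reached 0.483 for HMOX1, 0.234 for TXNRD1 and 0.219 for ABCC2, and that of NQO1 with BRSK2 lay between 0.062 and 0.531.

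The NRF2 list's median was -0.08 with BRSK2 (27 of 38 members negative; camera adjusted p = 0.0137, and adjusted p = 0.264 with an estimated correlation). It was -0.06 with BRSK1 (25 of 38 negative; camera adjusted p = 0.0213, and adjusted p = 0.455 with an estimated correlation). Without Mock replicate 2 neither call held (adjusted p = 0.126 and 0.112), and with BRSK1 it was also lost against Mock alone (adjusted p = 0.0651) and by fry (0.0641). Under library totals alone the medians were -0.19 and -0.10, against a shift of all genes' median by -0.102 with BRSK2. Over the alternatives the list's adjusted p lay between 0.000386 and 0.264 with BRSK2 and between 0.000293 and 0.455 with BRSK1. GCLM lost its call without BRSK2 replicate 3 (adjusted p = 0.0532) and against Mock alone (0.0774), and FTL with BRSK2 without BRSK2 replicate 3 (0.0652) and against hcRED alone (0.069). ME1 lost it without BRSK2 replicate 2 (0.179), BRSK2 replicate 3 (0.116), hcRED replicate 1 (0.0621), hcRED replicate 3 (0.118), Mock replicate 2 (0.0568) or Mock replicate 3 (0.0864), and BLVRB without BRSK2 replicate 1 (0.0574), BRSK2 replicate 3 (0.236), BRSK1 replicate 3 (0.0548), hcRED replicate 1 (0.0541), hcRED replicate 3 (0.145) or Mock replicate 3 (0.115). Over all alternatives run the adjusted p reached 0.191 for ME1 and 0.236 for BLVRB. With BRSK1, leaving out BRSK1 replicate 2 ended the calls of EPHX1 (0.0845) and FTL (0.0874), as did leaving out hcRED replicate 1 (0.053 and 0.0522) and the use of hcRED alone as control (0.0678 and 0.148). The list did not differ past the threshold between the kinases (camera adjusted p = 0.926) or between hcRED and Mock (adjusted p = 0.959). Of 20 NRF2 pathway regulators, 2 rose and 1 fell with BRSK2 (2 and 1 adjusted over the list alone), and the list did not pass (adjusted p = 0.955). MAFK, a small MAF protein and partner of NRF2, rose by 0.60 ± 0.08 (adjusted p = 4.64e-05).

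**Figure D2:**
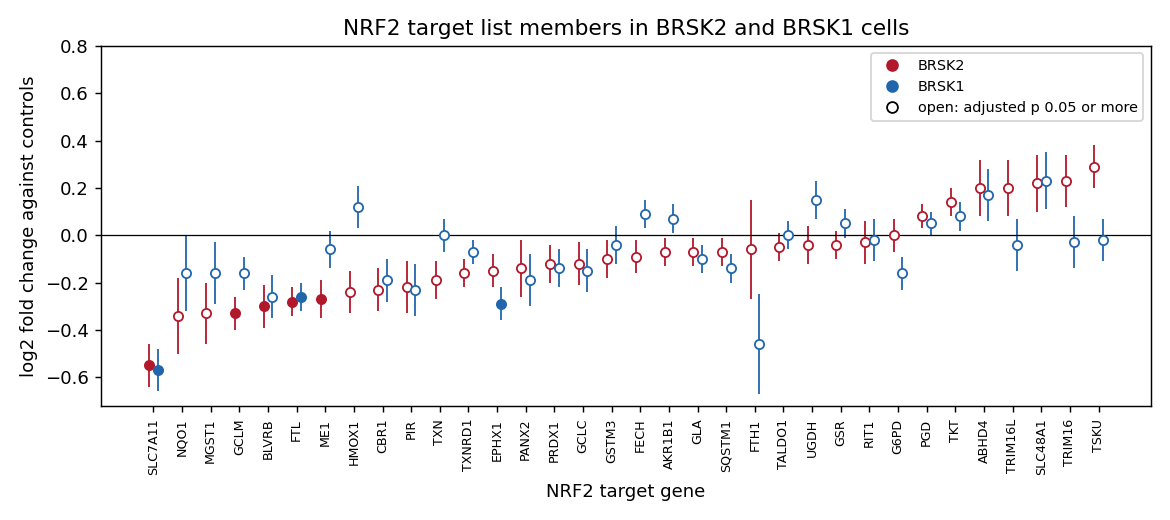
Log2 fold change against the controls (± SE) of the 34 NRF2 targets with a mean of at least 5 CPM, with BRSK2 (red) and BRSK1 (blue); filled points passed at an adjusted p under 0.05. With BRSK2 26 of the 34 were negative and with BRSK1 23, with SLC7A11 lowest for both.

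The same contrast was made for BRSK1. PTK2B, a focal adhesion-type tyrosine kinase, rose 2.41-fold (log2 fold change 1.27 ± 0.20 SE, n = 3 against 2 and 2, adjusted p = 0.00108), and TXNIP, the thioredoxin-interacting protein, 2.33-fold (1.22 ± 0.13). AMOTL2 (0.96 ± 0.12), PIM1 (0.93 ± 0.09), WNT9A (0.93 ± 0.14) and ZC3H6 (0.89 ± 0.12) also rose. Among the decreases were F12, coagulation factor XII (-0.78 ± 0.16), and C9orf172 (-0.73 ± 0.15). edgeR's quasi-likelihood test called 1089 genes, 638 higher and 451 lower, with a median absolute log2 fold change of 0.35. Of these, 61 were more than 2-fold higher and 8 more than 2-fold lower.

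The mitochondrially encoded messenger RNAs were the list with the smallest p for BRSK1. Of 13, 9 fell and 4 did not pass (11 fell adjusted over the list alone), with MT-ND2, a subunit of complex I, at -0.58 ± 0.09, MT-ATP6 at -0.52 ± 0.09 and MT-CO3 at -0.48 ± 0.10. The list's median was -0.47 (camera adjusted p = 6.26e-16; adjusted p = 0.301 with an estimated correlation). With BRSK2 the median was -0.21, 1 of the 13, MT-ND2, fell and 3 did adjusted over the list alone (camera adjusted p = 0.00213; adjusted p = 0.537 with an estimated correlation). In hcRED against Mock the median was -0.34 (camera adjusted p = 2.84e-10; adjusted p = 0.264 with an estimated correlation), and 7 of the 13 fell adjusted over the list alone. Against hcRED alone the calls of MT-ND2 (adjusted p = 0.087), MT-ATP6 (0.146) and MT-CO3 (0.203) with BRSK1 were lost, and so were the calls of the list (0.779) and of MT-ND2 (0.333) with BRSK2. The latter was also lost without BRSK2 replicate 2 (0.0715), BRSK2 replicate 3 (0.111), hcRED replicate 3 (0.0577) or Mock replicate 3 (0.0588). Mitochondrial transcripts took 4.17, 5.32 and 5.73% of all counts in BRSK1 replicates 1, 2 and 3, against 5.29 to 6.11% in the BRSK2 libraries, 5.82 and 6.48% in hcRED and 7.17 and 7.88% in Mock. BRSK1 replicate 1, in which keratin transcripts also stood highest, was the lowest, and without it the list's median with BRSK1 was -0.32 (camera adjusted p = 2.51e-09).

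Of 25 p53 targets, 7 rose with BRSK1 and 18 did not pass (10 rose adjusted over the list alone), with the cell cycle inhibitor CDKN1A at 0.48 ± 0.08 and the list's median at 0.21 (camera adjusted p = 5.62e-06; adjusted p = 0.301 with an estimated correlation). The p53 list was also higher in hcRED than in Mock (median 0.16, camera adjusted p = 0.000425), and CDKN1A lost its call against hcRED alone. Of 16 TGF-beta and BMP targets, 4 rose and 1 fell (5 and 1 adjusted over the list alone), with SMAD7 at 0.70 ± 0.08 and KLF10 at 0.67 ± 0.11. Of 19 YAP and TAZ targets, 4 rose, and 7 adjusted over the list alone. The camera adjusted p was 0.00154 and 0.0128, with adjusted p = 0.301 with an estimated correlation for each, and the YAP and TAZ call was lost against Mock alone (adjusted p = 0.209). BBC3 (0.54 ± 0.10) and BCL2L13 (0.35 ± 0.07) were among 6 of 18 BCL2 family genes that rose (6 adjusted over the list alone). The BCL2 family call (camera adjusted p = 0.0299; adjusted p = 0.301 with an estimated correlation) was lost without BRSK1 replicate 3 (adjusted p = 0.0702), hcRED replicate 1 (0.0778) or Mock replicate 3 (0.0825), and against hcRED (0.0534) or Mock (0.0561) alone. Of 27 immediate early genes, 4 rose and 1 fell (7 and 1 adjusted over the list alone; camera adjusted p = 0.0299, adjusted p = 0.479 with an estimated correlation). That call was lost without BRSK1 replicate 3 (adjusted p = 0.0764), hcRED replicate 1 (0.079) or Mock replicate 3 (0.0825), and against Mock alone (0.075). CDT1 (0.62 ± 0.07) and E2F1 (0.28 ± 0.06) rose as with BRSK2, and HMMR, a mitotic spindle protein, rose by 0.40 ± 0.06, while the G1 and S phase list (camera adjusted p = 0.366) and the G2 and M phase list (0.115) did not pass camera, the latter being called higher by fry (adjusted p = 0.0498).

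Proteasome and tubulin lists fell with BRSK1 too. Of 34 proteasome genes, 3 fell, and 12 fell and 1 rose adjusted over the list alone (median -0.11, camera adjusted p = 2.13e-05; adjusted p = 0.301 with an estimated correlation). Of 28 tubulins and microtubule-associated proteins, 8 fell and 11 did adjusted over the list alone, with TUBB2A at -0.41 ± 0.08 (camera adjusted p = 8.82e-05; adjusted p = 0.301 with an estimated correlation). Of 24 glycolysis genes, 7 fell and 2 rose (11 and 3 adjusted over the list alone; camera adjusted p = 0.00154, adjusted p = 0.484 with an estimated correlation). Of 22 hypoxia targets, 5 fell, with the glucose transporter SLC2A1 at -0.41 ± 0.08, while 7 fell and 1 rose adjusted over the list alone (camera adjusted p = 0.00719; adjusted p = 0.462 with an estimated correlation). Of 36 ribosome biogenesis and MYC targets, 4 fell, and 6 fell and 2 rose adjusted over the list alone (camera adjusted p = 0.0119; adjusted p = 0.51 with an estimated correlation). Against hcRED alone these last 3 lists lost their calls (adjusted p = 0.461, 0.386 and 0.974). Hypoxia also lost its call without hcRED replicate 1 (0.0778), and ribosome biogenesis without hcRED replicate 1 (0.0778) or BRSK1 replicate 3 (0.174). These lists were lower in hcRED than in Mock as well, with medians of -0.16, -0.15 and -0.14 (camera adjusted p = 3.65e-07, 0.000223 and 2.84e-10), and adjusted p = 0.319, 0.264 and 0.264 with an estimated correlation, and there the hypoxia call was lost without hcRED replicate 3 (adjusted p = 0.125).

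Of the 15 lists called with BRSK1, 7 higher and 8 lower, none held with an estimated correlation and 7 also passed fry, in the same direction. Camera called nearly as many lists, 13, between hcRED and Mock, of which 0 passed fry. The gene count was 204 without BRSK1 replicate 3, 415 without BRSK1 replicate 2, 314 without hcRED replicate 1, 654 without hcRED replicate 3, 585 without Mock replicate 3 and 1751 without BRSK2 replicate 1, which enters this comparison only through the shared estimate of spread. Against hcRED alone 133 genes passed, 99 higher and 34 lower, and the calls of DUSP8 (1.05 ± 0.16 against all controls), GDF15 (1.73 ± 0.31), CDKN1A and SLC2A1 were lost (adjusted p = 0.119, 0.104, 0.0677 and 0.0535). Against Mock alone 1133 passed, 602 higher and 531 lower, so the BRSK1 count depended strongly on the control used. Under library totals alone 463 genes were higher and 733 lower. In the authors' deposited table for BRSK1, 879 genes were listed, 523 higher and 356 lower, with adjusted p up to 0.0496. All 879 of the authors' deposited table had the same direction here and 805 were called.

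**Figure D3:**
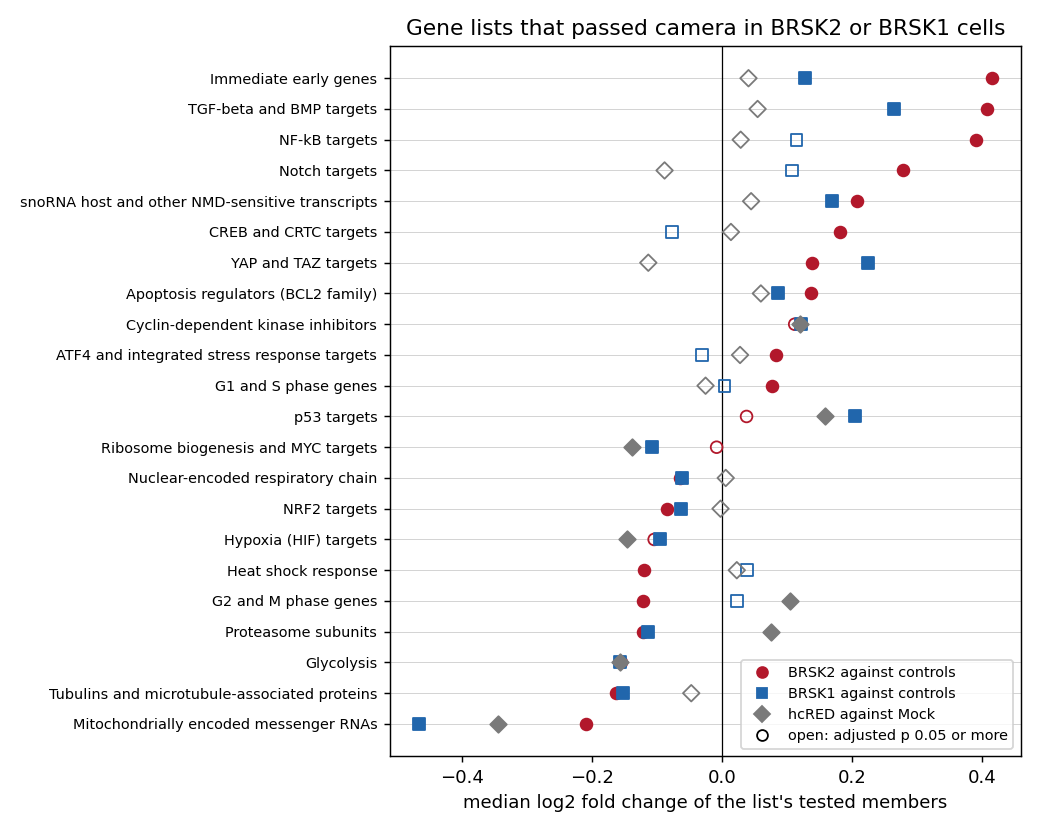
Median log2 fold change of the tested members of the 22 gene lists that passed camera with BRSK2 or BRSK1, for BRSK2 (circles) and BRSK1 (squares) against the controls and hcRED against Mock (diamonds); filled symbols had an adjusted p under 0.05. The immediate early list was highest with BRSK2 (0.42) and the mitochondrially encoded messenger RNAs lowest with BRSK1 (-0.47); under library totals alone the BRSK2 medians of the ATF4 list and of the G1 and S phase list turned to -0.02 and -0.03.

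To ask how far the kinases changed the same genes, the calls of both comparisons were set side by side without BRSK1 and BRSK2. Both kinases raised WNT9A, AMOTL2, PIM1, SMAD7, KLF10, CDT1 and BBC3 and lowered SLC7A11 and TUBB2A. In all, 479 genes were called in the same direction with both, 338 higher and 141 lower, and none in opposite directions. Independent lists of these sizes among 16934 genes would share 30.4 higher and 13.8 lower. Because both comparisons used the same controls, 20 simulations of unchanged groups were run. These shared 0 calls, but with 0.25 higher and 0.15 lower calls on average in one comparison and 0.05 and 0.2 in the other they had almost none to share, so this count does not show how much of the overlap the shared controls give, and part of it may come from them. Across genes, which are not independent replicates, the fold changes had r = 0.61 and a covariance of 0.0786, against r = 0.44 and a covariance of 0.0254 (highest 0.0279) in the simulations. With the controls split, BRSK2 against hcRED and BRSK1 against Mock shared 139 calls (112 higher and 27 lower, 13.3 and 7.2 for independent lists; 7 opposite; r = 0.21, covariance 0.0358). BRSK2 against Mock and BRSK1 against hcRED shared 71 (61 higher and 10 lower, 3.5 and 0.7 for independent lists; r = 0.23, covariance 0.038). The overlap was 983 without BRSK2 replicate 1, 260 without BRSK2 replicate 2, 174 without BRSK2 replicate 3, 239 without BRSK1 replicate 2, 120 without BRSK1 replicate 3, 146 without hcRED replicate 1, 287 without hcRED replicate 3 and 236 without Mock replicate 3.

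The kinases were then compared directly, 3 libraries against 3. JUNB, an AP-1 subunit, was 1.92-fold higher with BRSK2 (log2 fold change 0.94 ± 0.12 SE, adjusted p = 0.000134). DUSP1 was also higher with BRSK2 (0.64 ± 0.09, adjusted p = 0.000944). HSPA6, an inducible HSP70 protein with close paralogs, was higher with BRSK1, at 5.68 against 0.478 CPM (-3.60 ± 0.44, adjusted p = 0.000944). These 3 calls held in each alternative that gave an adjusted p, with values up to 0.00496, 0.0245 and 0.0451. Besides BRSK1 (-11.18 ± 0.33) and BRSK2 (10.18 ± 0.17), the 59 genes called, 39 higher and 20 lower with BRSK2, included WNT9A (0.74 ± 0.14), SESN2 (0.51 ± 0.08), E2F1 (0.34 ± 0.06), DNAJB1, an HSP40 co-chaperone (-0.37 ± 0.06), and TOP2A (-0.29 ± 0.06).

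Among the lists, G2 and M phase genes were lower with BRSK2 than with BRSK1 (median -0.16; 1 of 36 lower, 17 adjusted over the list alone; camera adjusted p = 3.32e-13), the only list of this comparison that held with an estimated correlation (adjusted p = 0.0352 with an estimated correlation). Of the 11 lists called between the kinases, 5 also passed fry, in the same direction. Immediate early genes were higher (median 0.35; 3 of 27 higher, 11 adjusted over the list alone; camera adjusted p = 1.13e-12, adjusted p = 0.072 with an estimated correlation). ATF4 targets were higher (median 0.16; 3 of 38 higher, and 11 higher and 1 lower adjusted over the list alone; camera adjusted p = 3.3e-08, adjusted p = 0.0536 with an estimated correlation). Heat shock response genes were lower (median -0.12; 2 of 25, and 2 adjusted over the list alone; camera adjusted p = 1.73e-05, adjusted p = 0.072 with an estimated correlation). CREB and CRTC targets, which share DUSP1 and other members with the immediate early list, were higher (2 of 17, and 5 adjusted over the list alone; camera adjusted p = 0.00113, adjusted p = 0.164 with an estimated correlation). NF-kB targets were higher (1 of 15, and 2 adjusted over the list alone; camera adjusted p = 0.00874, adjusted p = 0.246 with an estimated correlation), but not past the threshold without BRSK2 replicate 3 (adjusted p = 0.106) or BRSK1 replicate 1 (0.0739). The 5 tested markers of other carcinoma lines were lower with BRSK2, at a median of -1.92 (camera adjusted p = 0.0323; adjusted p = 0.503 with an estimated correlation). The keratins KRT5, KRT14 and KRT17 were highest in BRSK1 replicate 1, with KRT14 at 33.4 CPM against at most 9.84 elsewhere. Without that library the carcinoma list had an adjusted p of 0.858, without BRSK2 replicate 3 one of 0.229, and under library totals alone one of 0.124.

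Single libraries decided much of this comparison. The count was 7 without BRSK2 replicate 3 or BRSK1 replicate 1, 8 without BRSK1 replicate 2, 12 without BRSK1 replicate 3, 15 without BRSK2 replicate 2, 22 without hcRED replicate 1 and 21 without hcRED replicate 3. WNT9A lost its call without BRSK2 replicate 3 (adjusted p = 0.127), BRSK1 replicate 1 (0.103) or BRSK1 replicate 2 (0.0894), SESN2 without BRSK2 replicate 2 (0.0764), BRSK2 replicate 3 (0.0783), BRSK1 replicate 1 (0.0677) or BRSK1 replicate 2 (0.0894), E2F1 without BRSK2 replicate 2 (0.0605), BRSK2 replicate 3 (0.125), BRSK1 replicate 2 (0.0894) or BRSK1 replicate 3 (0.101), and DNAJB1 without BRSK2 replicate 3 (0.111), BRSK1 replicate 1 (0.0598) or BRSK1 replicate 3 (0.0684). TOP2A lost its call without BRSK2 replicate 2, without BRSK2 replicate 3 and without each BRSK1 or hcRED library, with an adjusted p up to 0.138. With a correction for GC content, chosen after the data were seen, 10 genes passed, 4 higher and 6 lower, 9 of them among the 59, and with GC content and length corrected 5 were higher and 8 lower. The GC correction ended the calls of WNT9A (adjusted p = 0.0725), SESN2 (0.14), E2F1 (0.175) and TOP2A (0.237). DESeq2 called 190 genes, which held 42 of the 59 in the same direction, and under library totals alone 24 genes were higher and 182 lower.

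As background, the control groups were compared with each other, 2 libraries against 2. TP53INP1, a p53-inducible gene, was higher in hcRED than in Mock (0.79 ± 0.14, adjusted p = 0.048), and ARHGAP22 (-0.64 ± 0.10, adjusted p = 0.0182), RP6-24A23.8 (-0.63 ± 0.11), RP6-24A23.7 (-0.58 ± 0.09) and the neurofilament gene NEFM (-0.42 ± 0.08) were lower. These 5 genes were the calls of edgeR's quasi-likelihood test, while 1516 had an unadjusted p under 0.05, DESeq2 called 52 genes and limma-voom 2. RP6-24A23.7 and RP6-24A23.8 lie next to each other on chromosome X and were counted as separate genes. Under library totals alone 4 genes were higher and 3 lower. The count was 49 without BRSK2 replicate 1, 3 without BRSK2 replicate 2, 2 without BRSK2 replicate 3, BRSK1 replicate 2 or BRSK1 replicate 3, 18 without hcRED replicate 1, 9 without Mock replicate 2 and 0 without hcRED replicate 3 or Mock replicate 3. Of 13 lists that passed camera, 6 higher and 7 lower, p53 targets were higher in hcRED (median 0.16, 1 of 25 higher, camera adjusted p = 0.000425) and G2 and M phase genes too (median 0.11, camera adjusted p = 0.000184). None of the 13 held with an estimated correlation, where their adjusted p lay between 0.264 and 0.661, and none passed fry.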

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

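The GC corrections and the list tests without single libraries or against a single control were chosen after the results were seen, and for the changes below the cause was not tested unless stated. In the order BRSK2 against controls, BRSK1 against controls, BRSK2 against BRSK1 and hcRED against Mock, the counts of genes were 1325, 1089, 59 and 5. Library totals alone gave 3001 for BRSK2 and 206 between the kinases; no filter gave 188 between the kinases and 128 for hcRED against Mock, and the filter at 1 CPM gave 3 for the latter. DESeq2 gave 190 and 52 for the last 2 comparisons, limma-voom 2 for hcRED against Mock, and no robust estimation 14 and 0. An adjusted p under 0.01 left 474, 256, 6 and 0 by its construction. Fits of only the groups compared gave 20 between the kinases and 0 for hcRED against Mock, where fewer samples estimate the spread. With hcRED alone as control 606 (BRSK2) and 133 (BRSK1) passed, and with Mock alone 931 and 1133. The GC correction left 10 between the kinases, and GC and length correction 13, and 16 for hcRED against Mock. The replicate number as a block gave 2153, 1999, 267 and 434, and an overlap of 965 against 479. Same-numbered libraries deviated from their group means with correlations of -0.05 to 0.16 and others with -0.14 to 0.10. Of the 10 libraries 6 correlated best with their own number, and 1 of 3 BRSK2 and BRSK1 pairs was over 0.1. In a group of 2 libraries the deviations mirror each other, so these correlations cannot decide whether the numbers pair the samples. With the block the Notch list lost its call between the kinases (adjusted p = 0.0547) and translation factors theirs in hcRED against Mock (0.061), and no other list call was lost. In BRSK2 against controls the block also called BRSK1 (adjusted p = 5.16e-06) and, among NRF2 targets, HMOX1 (0.0306), TXNRD1 (0.0387) and TXN (0.02) as lower and ABCC2 (0.0317), TSKU (0.0349) and TKT (0.0499) as higher. The overlap was 139 and 71 with the controls split. The NRF2 list's medians of -0.084 (BRSK2) and -0.062 (BRSK1) kept their direction throughout, at -0.189 and -0.100 under library totals alone and -0.091 and -0.096 with GC and length corrected, but lost their calls with an estimated correlation (-0.084, adjusted p = 0.264, and -0.062, 0.455), and with BRSK1 by fry (-0.062, 0.0641) and against Mock alone (-0.109, 0.0651). Lists called fell from 18, 15, 11 and 13 to 0, 0, 1 and 0 with an estimated correlation, and to 0 by fry for hcRED against Mock. Leaving out 1 library gave 346 to 2211, 204 to 1751, 7 to 64 and 0 to 49 genes, an overlap of 120 to 983, NRF2 medians of -0.126 to -0.066 (BRSK2) and -0.093 to -0.059 (BRSK1), and 15 to 20, 9 to 16, 8 to 13 and 8 to 14 lists, of which 13, 7, 6 and 6 of those called held each time. Among the 623 named genes by comparison, 14519 of 16051 values stayed on their side of the threshold, while 1148 lost and 384 gained a call. Of the values called in the main fit or the alternative, 0 reversed direction. For genes called in neither, direction was not compared, and such genes, many of them list members without a call, could only stay or gain a call. A count of 0 in a library allows a level of up to 0.123 to 0.182 CPM (3 counts, counting error only), and how far depth limits the calls of genes with few counts was not tested.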

Other observations

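The tests of the keratins and of the tubulins, the corrections for GC content, and the list tests without single libraries or against a single control were chosen after the results were seen. Further gene groups were measured besides those described above. With BRSK1, PRKAG1, a regulatory subunit of AMPK, rose by 0.45 ± 0.08 (SE, n = 3 against 2 and 2), in a list of 23 AMPK-related kinases and subunits of which 3 rose, and 3 adjusted over the list alone, and which did not pass as a list (camera adjusted p = 0.131). MSMO1, an enzyme of cholesterol synthesis, rose by 0.35 ± 0.07, 1 of 2 of the 24 cholesterol synthesis genes that did (2 adjusted over the list alone; camera adjusted p = 0.207). Of 8 cyclin-dependent kinase inhibitors, 2 rose with BRSK1, CDKN1A and CDKN2D (0.64 ± 0.16), and 3 adjusted over the list alone (camera adjusted p = 0.0299; adjusted p = 0.466 with an estimated correlation). The call of CDKN2D was lost without BRSK1 replicate 2 (adjusted p = 0.0812), BRSK1 replicate 3 (0.0718) or hcRED replicate 1 (0.0641), against hcRED alone (0.532) and with the controls as 1 group (0.0985), and the list's call was lost without BRSK1 replicate 1 (adjusted p = 0.0516), BRSK1 replicate 3 (0.0961), hcRED replicate 1 (0.079) or Mock replicate 2 (0.111), and against hcRED alone (0.405). That list was also higher in hcRED than in Mock (median 0.12, camera adjusted p = 0.0167; adjusted p = 0.449 with an estimated correlation), a call lost without hcRED replicate 3 (adjusted p = 0.146) or Mock replicate 2 (0.219). Of 72 nuclear-encoded respiratory chain genes, 5 fell with BRSK1, as did 5 adjusted over the list alone (camera adjusted p = 0.0299; adjusted p = 0.783 with an estimated correlation), and this was lost without BRSK1 replicate 1 (adjusted p = 0.394), BRSK1 replicate 3 (0.0549), hcRED replicate 1 (0.366) or Mock replicate 2 (0.809), and against Mock alone (0.0986). Of 21 snoRNA host and other NMD-sensitive transcripts, 1 rose with BRSK1, and 1 adjusted over the list alone (camera adjusted p = 0.00792; adjusted p = 0.538 with an estimated correlation), a call lost without BRSK1 replicate 2 (adjusted p = 0.165) or Mock replicate 3 (0.103). Without BRSK2 replicate 1, which enters only through the shared estimate of spread, SNHG1 (adjusted p = 0.00192) and TAF1D (0.00157) were also called higher with BRSK1, and over all alternatives run their adjusted p reached 0.436 and 0.524.

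Between the kinases, mitochondrially encoded messenger RNAs were higher with BRSK2 (median 0.25, camera adjusted p = 2.9e-07; adjusted p = 0.389 with an estimated correlation), with none of the 13 called singly. That median was 0.11 without BRSK1 replicate 1 (adjusted p = 0.0217) and 0.15 without BRSK2 replicate 1 (0.000315). Ribosome biogenesis and MYC targets were higher (median 0.09, camera adjusted p = 0.00396; adjusted p = 0.609 with an estimated correlation; lost without BRSK1 replicate 3, adjusted p = 0.177, and under library totals alone, 0.0975, where the median was 0.02). p53 targets were lower (median -0.13, camera adjusted p = 0.00874; adjusted p = 0.401 with an estimated correlation; lost without BRSK2 replicate 1, adjusted p = 0.222, or BRSK1 replicate 3, 0.0663). Notch targets were higher (median 0.12, camera adjusted p = 0.0312; adjusted p = 0.33 with an estimated correlation). The Notch call was lost without BRSK2 replicate 2 (adjusted p = 0.129), BRSK2 replicate 3 (0.0678), BRSK1 replicate 1 (0.0628) or BRSK1 replicate 2 (0.128), and with the GC correction (0.324). On a principal component analysis of the 10 libraries, BRSK2 replicate 1 stood apart on the third component (11.7% of the variance), at -33.9. On the first component (21.7%), replicate 1 of BRSK2 (-1.1) and of BRSK1 (0.7) lay between the other kinase libraries (-29.4 to -14.2) and the controls (10.2 to 35.6).

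Other splits of the same libraries were tested with the controls as 1 group. For BRSK2, 1 of the 35 splits of the 7 libraries, the real one, gave as many genes (804, against 39 at most in the others). For BRSK1 it was also 1 of 35 (898 against 491, the latter from the split that put hcRED replicate 3 with the BRSK1 libraries). No other arrangement of these libraries thus gave as many genes for either kinase. The other splits put any group difference into the spread and so tend to call fewer genes. They cannot exclude differences between libraries that follow the groups. The 6 libraries of the kinases make 10 splits, too few for a share under 0.05, and the real split, 1 of the 10, gave 20 genes and the highest other 19. BRSK1 and BRSK2, which differ by design, were not left out of these counts, so 20 against 19 does not place the real split first.

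Keratins and other squamous epithelial transcripts stood highest in BRSK1 replicate 1. Of 25 markers with 1 CPM or more in some library, from a list of 27 that was partly chosen after the data were seen, 24 (96%) were highest there, with KRT14 at 33.4 CPM, KRT5 at 29.9, KRT6A at 28.3 and KRT17 at 20.3, and DSC3, the exception in level, near 100 in every library. An effect of BRSK1 is argued against by the other 2 BRSK1 libraries, in which the median log2 ratio of the markers over the 4 controls was -0.81. Reads or RNA of a squamous epithelial cell type may therefore be the source, as a hypothesis, since the listed markers without DSC3 together made up 182 CPM there against 8.05 to 40.4 elsewhere. How such material would have entered stays open.

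Genes higher with BRSK2 had a higher GC content (median 56.6%) than those lower (44.2%), and all tested genes had 49.2%. With BRSK1 the medians lay the other way, at 49.2% for genes higher and 54.4% for those lower. With each library's trend with GC content removed, 4.7% of the gap with BRSK2 stayed and 77.9% of the BRSK2 calls (1032 of 1325) kept their direction and threshold. The trend, as the difference between the GC-richest and GC-poorest 10% of genes in the median log2 ratio to the mean of the controls, was 0.13, 0.15 and 0.09 in the BRSK2 libraries and -0.21 to 0.10 in the others. A GC content bias of the libraries could give this gap, but the correction removes any trend with GC content, whatever its source, so such a bias and a response of GC-rich genes to BRSK2 cannot be told apart. Between the kinases 10 genes passed after the correction, 4 higher and 6 lower with BRSK2 against 39 and 20 before it, and 9 of them were among the 59.

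Tubulin transcripts were lower with BRSK2. The 12 alpha and beta tubulin genes had a median log2 fold change of -0.30, 9 of them negative and 6 called lower, against -0.08 for the 16 other members of the list. The 3 others of the 12 were positive and did not pass: TUBB3 at 1.17 ± 0.76 (adjusted p = 0.376) and TUBA8 at 0.50 ± 0.48 (adjusted p = 0.584), both under 1 CPM in every library, and TUBB2B at 0.15 ± 0.07 (adjusted p = 0.173). Reads shared between paralogs would leave their sum level, but the summed counts changed by -0.25 ± 0.07 (SE, adjusted p = 0.0214; 0.066 against hcRED alone and 0.0681 against Mock alone). A decline shared by most alpha and beta tubulin genes, which may reflect the cell's known degradation of tubulin transcripts when free tubulin rises, stays a hypothesis, since tubulin protein was not measured here. BRSK1 gave a sum of -0.25 as well (adjusted p = 0.0296; 0.127 against hcRED alone and 0.0687 against Mock alone).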
